A study of Mus musculus with 12 samples.

How the data were processed

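Biotin-labelled total RNA, extracted with Trizol from the spleens of 12 mice, was hybridised to 12 Affymetrix 3' expression arrays, 1 mouse per array. Per the labels, 6 mice were wild type (wt) and 6 lacked Il1rn (ko), all on the BALB/c background, with 3 mice of each genotype at 1 month and 3 at 4 months. The deposited values are signal intensity per probe set on a linear scale, and the authors' processing notes name MAS5 without a version. Tested on the values, each array already had a 2% trimmed mean of 500, so the scaling repeated here changed no call. Detection calls and scan dates were not used here. The array holds 45101 probe sets, of which 64 are Affymetrix controls and were left out. The annotation gave 1 gene symbol to 34958 probe sets, several to 932 and none to 9211. Gene order was taken from a gene table of the mouse assembly GRCm38.p6, and no coordinates are given because the build behind the array annotation is not named.

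Each array was scaled to a 2% trimmed mean of 500, an offset of 32 was added, and values were transformed to log2. Probe sets with a scaled signal of at least 100 in at least 3 of the 12 arrays were tested, which left 27041. Linear models with 4 group means were fitted with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend in the prior variance. There were 8 residual degrees of freedom and 8.27 prior degrees of freedom. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the probe sets tested, with 2-sided tests. The 6 contrasts were ko against wt at 1 month, at 4 months and over both ages, the difference of the genotype effect between the ages, and 4 months against 1 month in wt and in ko. Errors of log2 differences are standard errors (SE) from limma, and errors of scaled signals are standard deviations (SD) over 3 mice. The number of arrays limits the precision of every value.

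The 27 gene lists covered IL-1 family and receptor signalling, inflammatory cytokines with chemokines and NF-kB targets, T helper 17 and T helper cytokines, neutrophil precursor granules, mature neutrophils, erythroid cells and haem synthesis, megakaryocytes and platelets, mast cells with basophils and eosinophils, monocytes with macrophages and red pulp macrophages, dendritic cells, T cells, B cells, plasma cells and secreted immunoglobulin, germinal centre B cells, NK and cytotoxic cells, MHC class II antigen presentation, interferon-stimulated genes, cell cycle, complement and acute phase, bone and cartilage remodelling, splenic stroma and extracellular matrix, endothelial cells, pancreas, adipose tissue, skeletal muscle, immediate early and heat shock genes, and sex-linked transcripts. Of these, 26 with at least 5 measured members were tested with limma's camera at a preset inter-gene correlation of 0.01, over 12339 genes with 1 probe set each, the one with the highest mean. Camera compares the genes of a list with all other genes, and its p was adjusted over the lists within a contrast. Beside it stand camera with an estimated correlation, limma's fry, the number of members called over all probe sets and the number adjusted over the list alone. Some genes belong to more than 1 list.

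The gene lists, the model, the comparisons and the rule for naming genes were fixed before the data were examined. The rule named Il1rn, then for the genotype effect at each age and for age in wt the 10 genes with the largest and the 10 with the smallest log2 difference among called probe sets with 1 symbol and no overlap between the 2 groups. For the other contrasts it named the first 5 each way, and it added up to 4 members with the smallest p of each list with a camera call or at least 2 called members. Genes named outside the rule are said to be so. A further 5 lists were written after the data were seen: heat shock genes and immediate early genes (the fixed list split into 2 parts), melanocyte genes, clock-controlled genes, and clock genes of opposite phase. Their camera p was adjusted within a contrast over these added lists alone.

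The test was checked on simulated data with 27041 probe sets, 100 of them changed by a log2 of 1 and a further 100 by a log2 of 2. At a log2 change of 1 it recovered 49 of the 100 in ko against wt at 1 month and 44 at 4 months, and at a log2 change of 2 it recovered 97 and 96, with 11 and 7 false calls. For the difference of the genotype effect between ages it recovered 23 of 100 at a log2 change of 1 and 67 at 2. A simulated shift of the mature neutrophil list was recovered, with 0 of the 25 other lists called. The noise was drawn independently for each gene, so this check could not show false list calls that come from correlation between genes.

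The alternatives were quantile normalization, no further scaling, centring each array on its median, offsets of 1, 8 and 64, no filter and a filter at 200, eBayes without a trend and with robust hyperparameters, array weights, an adjusted p under 0.10, an added limit of 2-fold, the replicate number as a block, fits on only the 6 arrays compared, and leaving out each array in turn. For the lists they were an estimated correlation, fry, the mean of a gene's probe sets and the probe set with the largest variance. Because the highest signal per array fell into a low and a high set, divided at 45000, fits with that set as a block, with set and replicate block, and within each set were added after the data were seen. Il1rn was then refitted in every setting whose filter keeps it. Neighbours of Il1rn were the 200 protein-coding genes on each side of it or, where fewer lie before the end of the chromosome, those (105 on one side). Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.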

Results

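Gene expression was measured in the spleens of 12 BALB/c mice, 3 in each of 4 groups: wt at 1 month, ko at 1 month, wt at 4 months and ko at 4 months. Il1rn encodes the IL-1 receptor antagonist, which blocks IL-1 signalling, and BALB/c mice that lack it develop arthritis spontaneously. The study's title asks for arthritis-related genes that are specific to a phase. The median signal of an array lay between 113 and 148, and between 52.1% and 59.2% of probe sets reached a scaled signal of 100. The ratio of 3' to 5' signal was 0.649 to 0.816 for Gapdh and 1.07 to 1.20 for actin, except in wt at 4 months replicate 1, with 0.999 and 1.37. Across all tested probe sets, Pearson's r between 2 arrays was 0.944 to 0.983 within a group and 0.878 to 0.980 between groups. The first principal component held 39.8% of the variance and the second 15.6%. In wt at 4 months replicate 2, genes of the pancreas, which lies beside the spleen, stood a mean of 5.50 log2 units above the median of the arrays, and in the other 11 arrays between -0.27 and 0.45. The highest deposited signal of an array was 33427 to 37921 in 6 arrays (the low set) and 51247 to 68987 in the other 6 (the high set). All 3 ko arrays at 1 month were in the low set, while wt at 1 month had 1 low and 2 high arrays and each group at 4 months also had arrays of both sets. The low wt array at 1 month, replicate 3, had an r of 0.970 to 0.980 with the 3 ko arrays of that age. With the other wt arrays of that age it had 0.944 and 0.959. On the second component it stood at 11.3, the ko arrays at 8.10 to 30.1 and the other wt arrays at -51.4 and -45.6. At 1 month these measures placed it with its array set and not with its genotype.

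**Figure D1:**
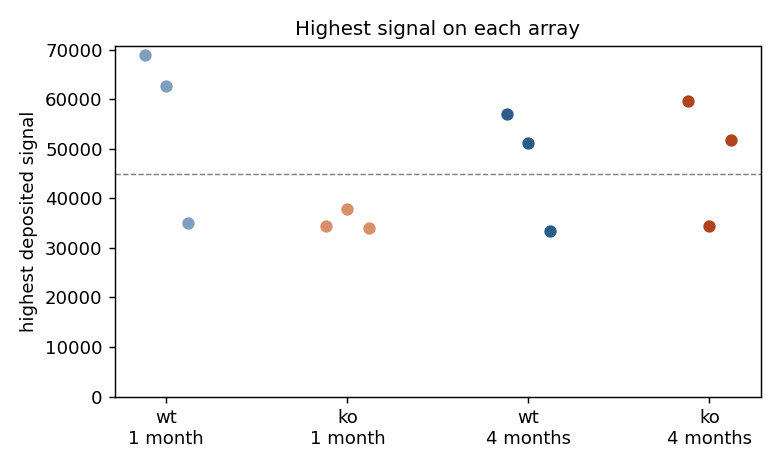
Highest deposited signal (vertical axis, linear scale from 0) of each array, by group, with the dashed line at 45000 that divides the low from the high set. The 3 ko arrays at 1 month all lie at or below 37921, while each of the other groups has arrays on both sides.

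Il1rn was lower in ko spleens at both ages. Of its 3 probe sets, the one with the largest genotype difference had a scaled signal of 142 ± 21.5 (SD, n = 3) in wt and 23.3 ± 17.5 in ko at 1 month, and 209 ± 61.5 in wt and 21.9 ± 16.6 in ko at 4 months. The log2 difference was -1.70 (SE 0.35, limma adjusted p = 0.0403) at 1 month, -2.17 (SE 0.35, limma adjusted p = 0.0034) at 4 months and -1.94 (SE 0.25, limma adjusted p = 0.000428) over both ages. The 3 ko arrays lay below the 3 wt arrays at each age. A second probe set was called only over both ages, at -0.85 (SE 0.22, limma adjusted p = 0.0371). The remaining one was not called in any genotype contrast, with -0.96 (SE 0.56) at 1 month and -0.76 (SE 0.56) at 4 months. The call at 1 month was lost without ko replicate 1, 2 or 3 (limma adjusted p = 0.0945, 0.0554 and 0.257), without wt replicate 1 or 2 (0.118 and 0.196) and with the array set as a block (0.202). It was also lost with quantile normalization (0.0511), median centring (0.0501), offsets of 1 and 8 (0.0897 and 0.0698), no filter (0.0605), array weights (0.0661) and only the 6 arrays compared (0.127). The replicate block (0.0557), both blocks (0.275) and the low set, with 1 wt array (0.633), ended it as well. The 4-month call held without each array in turn. It was lost within the low set, 1 ko against 1 wt array (0.0666), and within the high set, 2 against 2 (0.143).

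**Figure D2:**
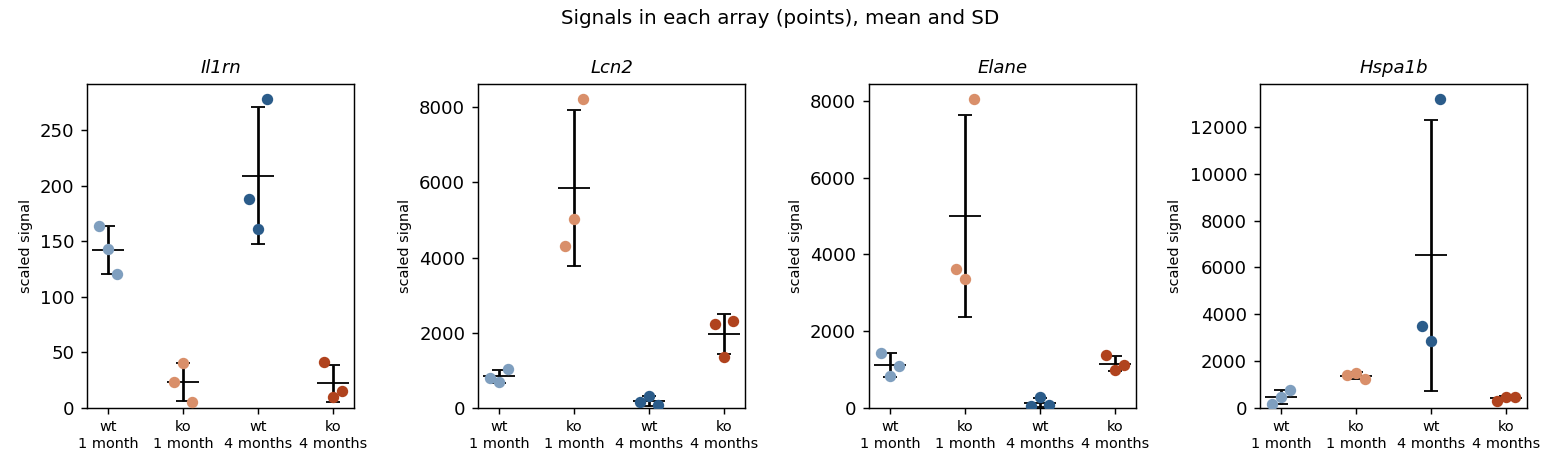
Scaled signals (vertical axes, linear scale from 0) of Il1rn, Lcn2, Elane and Hspa1b in each array (points), with the mean (bar) and SD (whiskers) of the 3 mice of each group. Il1rn lies between 5.64 and 40.8 in the 6 ko arrays and between 120 and 278 in the 6 wt arrays.

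At 1 month, ko spleens held far more transcript of neutrophil granule proteins than wt spleens. Lcn2, which encodes the iron-sequestering protein lipocalin-2, rose 6.62-fold, from 835 ± 180 to 5855 ± 2083 (SD, n = 3). Prtn3 (proteinase 3) rose by 2.65 log2 units (SE 0.24), Mpo (myeloperoxidase) by 2.27 (SE 0.25) and Ltf (lactoferrin) by 2.29 (SE 0.27). On the other side, Oas1a, a 2'-5'-oligoadenylate synthetase of the antiviral response, fell by 2.95 (SE 0.31), and Mcpt4, a mast cell protease, fell by 2.87 (SE 0.26). Of 27041 probe sets, 120 were called at limma adjusted p under 0.05, 55 higher and 65 lower in ko. In all 120 the 3 ko arrays lay on 1 side of the 3 wt arrays, as they did in 19.9% of all tested probe sets, where chance gives 10%. The balance of directions depended on the scaling and the limits: 58 higher and 35 lower with median centring, 56 and 41 with quantile normalization, and 50 and 30 at 2-fold or more. It moved further towards lower with an adjusted p under 0.10 (130 higher and 262 lower) and with the filter at 200 (55 and 83).

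Of the 17 measured genes of the neutrophil precursor list, 13 were called higher at 1 month and 15 when adjusted over the list alone, with a median log2 difference of 1.84. Besides Prtn3 and Mpo they included Chil3 (2.37, SE 0.22), Ms4a3 (2.05, SE 0.25), Ctsg, which encodes cathepsin G (1.90, SE 0.21), and Elane, which encodes neutrophil elastase (2.05, SE 0.39). Of 19 mature neutrophil genes, 10 were called higher and 16 when adjusted over the list alone, with a median of 1.00. Cd177 rose by 2.57 (SE 0.25), Wfdc21 by 2.02 (SE 0.22), Hp (haptoglobin) by 1.97 (SE 0.24) and S100a9, a subunit of calprotectin, by 1.23 (SE 0.15). Both lists also passed camera with an estimated correlation (adjusted p = 0.0102 for each). Within the low set alone, 3 ko arrays against 1 wt array, the medians at 1 month were 2.06 for the precursor list and 1.41 for mature neutrophils. Pglyrp1, a peptidoglycan recognition protein stored in neutrophil granules, rose by 2.45 (SE 0.43), and Hdc, the enzyme that makes histamine, rose by 2.52 (SE 0.42).

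Other cell type lists moved down at 1 month with the preset correlation and lost that call with an estimated one. For B cells the median was -0.50, with 1 of 25 genes called lower and 16 when adjusted over the list alone (adjusted p = 0.0733 with an estimated correlation). The called gene, Cr2, which encodes complement receptor 2, fell by 0.71 (SE 0.15). For MHC class II antigen presentation the median was -0.45, with 0 of 16 called and 10 lower when adjusted over the list alone (adjusted p = 0.181 with an estimated correlation). For splenic stroma and extracellular matrix the median was -0.30, with Postn (periostin, -0.78, SE 0.15) and Col5a2 (a fibrillar collagen, -0.87, SE 0.18) called of 37 genes and 12 lower and 1 higher when adjusted over the list alone (adjusted p = 0.303 with an estimated correlation). For monocytes and macrophages the median was -0.27, with 1 of 28 called lower and, adjusted over the list alone, 5 lower and 1 higher (adjusted p = 0.0733 with an estimated correlation). That gene was Marco, a scavenger receptor of splenic marginal zone macrophages, at -1.50 (SE 0.22). Endothelial genes had a median of -0.22, with Cldn5, a tight junction protein, called of 24 (-0.75, SE 0.15) and 2 lower when adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). T cell genes (-0.20, 0 called over all or over the list alone of 27) and dendritic cell genes (-0.26, 0 called of 18, and 2 lower when adjusted over the list alone) both had an adjusted p = 0.303 with an estimated correlation. Small upward shifts were seen for megakaryocyte genes (0.27, adjusted p = 0.502 with an estimated correlation) and cell cycle genes (0.12, adjusted p = 0.582 with an estimated correlation), with 0 genes called in either, over all or over the list alone. Without wt replicate 3 the camera calls of dendritic cells, endothelial cells and the cell cycle were lost (adjusted p = 0.11, 0.11 and 0.0643). In the mast cell, basophil and eosinophil list, which passed neither test, Mcpt4 and Cpa3 (carboxypeptidase A3, -1.08, SE 0.19) were called lower and Hdc higher.

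Further genes lower in ko at 1 month were Oas1b (-2.72, SE 0.36), Ctps2, which encodes a CTP synthase (-2.47, SE 0.20), G530011O06Rik (-2.11, SE 0.35), Supt20 (-1.75, SE 0.34) and Il22ra2, a soluble IL-22 receptor (-1.43, SE 0.27). Tyrp1, a melanocyte enzyme, was also called lower (-3.83, SE 0.67), but its wt signal was 872 ± 912 (SD, n = 3), and the melanocyte gene Dct, named after its values were seen, was at 3099 and 1461 in wt replicates 2 and 3 and at 6.17 in wt replicate 1. With the array set as a block, 45 probe sets were called, 43 of them among the 120, and 32 were called within the low set alone, which holds 1 wt array at this age. The count was 63 without ko replicate 1, 67 without ko replicate 2, 36 without ko replicate 3, 41 without wt replicate 2 and 1590 without wt replicate 3. Of the 20 genes named by rule at this age, Il1rn and Il22ra2 lost their calls without wt replicate 1, these and Supt20 and Tyrp1 without ko replicate 2, and these 4 with Elane and Hdc without ko replicate 1. Without ko replicate 3, Elane, Hdc, Il1rn, Il22ra2, Pglyrp1, Tyrp1 and G530011O06Rik lost theirs, and without wt replicate 2 these and Supt20. The largest limma adjusted p in these fits was 0.203 for Elane, 0.115 for Hdc, 0.126 for Il22ra2, 0.136 for Pglyrp1, 0.23 for Supt20, 0.117 for Tyrp1 and 0.0728 for G530011O06Rik. The other 12, among them Lcn2, Prtn3, Mpo, Ltf, Cd177, Oas1a, Mcpt4 and Marco, kept their calls in each. With the array set as a block Elane, Hdc, Il1rn, Il22ra2, Pglyrp1, Supt20 and Tyrp1 lost theirs (limma adjusted p = 0.0598, 0.108, 0.202, 0.137, 0.104, 0.15 and 0.129). Supt20 did so with quantile normalization (0.0514), and Elane and Tyrp1 with an offset of 1 (0.0622 and 0.0779), where Tyrp1 was at -5.92.

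At 4 months, neutrophil genes were again higher in ko spleens, and erythroid, megakaryocyte and cell cycle lists were higher with the preset correlation but not with an estimated one. Lcn2 rose 10.1-fold, from 183 ± 125 to 1961 ± 530 (SD, n = 3). Ngp, which encodes neutrophilic granule protein, rose 8.55-fold, from 1229 ± 589 to 10174 ± 2030, and Camp, the antimicrobial peptide cathelicidin, 8.14-fold. Hspa1b, an inducible heat shock protein, fell by 3.57 log2 units (SE 0.48), from 6519 ± 5799 to 404 ± 82.4. Of 27041 probe sets, 621 were called at limma adjusted p under 0.05, 481 higher and 140 lower in ko, and 259 of them differed at least 2-fold, 209 higher and 50 lower. All 621 had no overlap between the 2 groups, as had 22.3% of all tested probe sets, where chance gives 10%.

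Of 17 neutrophil precursor genes, 12 were called higher at 4 months, with a median of 1.95, and 13 higher and 1 lower when adjusted over the list alone. Prtn3 rose by 3.19 (SE 0.24), Elane by 3.04 (SE 0.39), Mpo by 2.82 (SE 0.25) and Ctsg by 2.53 (SE 0.21). Of 19 mature neutrophil genes, 8 were called higher, with a median of 0.74, and 13 higher and 1 lower when adjusted over the list alone. S100a9 rose by 2.20 (SE 0.15), S100a8, the other subunit of calprotectin, by 2.14 (SE 0.15), Slpi, a protease inhibitor, by 1.56 (SE 0.16) and Lrg1 by 1.52 (SE 0.19). Both lists passed camera with an estimated correlation (adjusted p = 0.0454 for each). Within the low set alone, 1 ko against 1 wt array, and the high set alone, 2 against 2, the medians at 4 months were 2.23 and 2.02 for the precursor list and 0.44 and 0.94 for mature neutrophils. Ltf rose by 2.80 (SE 0.27).

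Among 37 erythroid and haem synthesis genes, 25 were called higher in ko and 33 when adjusted over the list alone, with a median of 0.94 (camera adjusted p = 1.63e-31; adjusted p = 0.0841 with an estimated correlation). Tal1, a transcription factor of blood progenitors and red cell precursors, rose by 1.25 (SE 0.16), Slc4a1, the red cell anion exchanger, by 1.14 (SE 0.16), Ank1, which anchors it to the membrane skeleton, by 1.45 (SE 0.21) and Rhag by 1.08 (SE 0.16). Among 20 megakaryocyte and platelet genes, 15 were called higher and 19 when adjusted over the list alone, with a median of 1.01 (adjusted p = 0.0552 with an estimated correlation). They included Alox12 (1.56, SE 0.22), the platelet receptors Clec1b (0.94, SE 0.13) and Gp5 (1.27, SE 0.19), and Tubb1, the platelet beta tubulin (1.23, SE 0.18). Among 63 cell cycle genes, 21 were called higher and 52 when adjusted over the list alone, with a median of 0.64 (adjusted p = 0.0841 with an estimated correlation). E2f8 rose by 1.25 (SE 0.19), the mitotic cyclin Ccnb2 by 1.00 (SE 0.19), and Ect2 and Kif11, which act in cell division, by 0.83 (SE 0.15) and 0.84 (SE 0.17).

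The list of immediate early and heat shock genes moved down at 4 months, with a median of -0.44, 6 of 31 called lower, and 15 lower and 2 higher when adjusted over the list alone (adjusted p = 0.0985 with an estimated correlation). Of the 6 called members, 5 encode heat shock proteins and their cochaperones and the other, named after its value was seen, is Ccn1 (-0.95). They include Dnajb1 (-1.20, SE 0.15), Dnaja1 (-1.35, SE 0.18), Hspa1b, and Hspa1a (-3.27, SE 0.55). Hsph1 fell by 1.78 (SE 0.32), and 1 probe set of Hspa8 fell by 1.97 (SE 0.25). Of the 3 wt arrays, replicate 3 had an Hspa1b signal of 13206 and the others 3482 and 2870, against 309 to 459 in ko.

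B cell genes had a median of -0.35, with 4 of 25 called lower and 7 when adjusted over the list alone (adjusted p = 0.0985 with an estimated correlation). These were Cd83 (-0.92, SE 0.19), Tnfrsf13c, the BAFF receptor (-0.76, SE 0.17), S1pr3 (-0.86, SE 0.19) and Spib, a B cell transcription factor (-0.65, SE 0.15). Germinal centre B cell genes had a median of -0.32, with Bcl6, a transcription factor of germinal centres, called of 13 (-0.80, SE 0.19) and 3 lower when adjusted over the list alone (adjusted p = 0.088 with an estimated correlation), and that camera call was lost without ko replicate 2 (adjusted p = 0.0687). Rag1, which starts antigen receptor gene rearrangement, fell by 1.82 (SE 0.41), and this call was lost without ko replicate 2, ko replicate 3 or wt replicate 1 (limma adjusted p = 0.131 at most). Small camera calls that did not hold with an estimated correlation were those of monocytes and macrophages (median 0.14, adjusted p = 0.262), T cells (-0.16, adjusted p = 0.623) and splenic stroma (-0.13, adjusted p = 0.633). Adjusted over the list alone, these had 3 higher and 1 lower, 0 and 0 genes, against 1 higher (Cd5l, 0.60, SE 0.15), 0 and 0 over all probe sets. The monocyte call was lost without ko replicate 2 or 3 or wt replicate 1 or 2 (adjusted p = 0.0736, 0.0607, 0.128 and 0.0802), the T cell call without ko replicate 2 or wt replicate 2 (0.431 and 0.224) and the stroma call without ko replicate 2 or wt replicate 3 (0.431 and 0.155).

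Further genes higher in ko at 4 months were Ighg3, an immunoglobulin heavy chain constant region (2.28, SE 0.25), and 6030468B19Rik (2.38, SE 0.26). Of 40 interferon-stimulated genes, which as a list passed neither test, Isg20 (1.15, SE 0.21), Oas3 (1.02, SE 0.23) and Irf7 (1.03, SE 0.25) were called higher and Oas1a lower (-3.37, SE 0.31), against 7 higher and 2 lower when adjusted over the list alone. Oas1b (-2.90, SE 0.36), Ctps2 (-2.39, SE 0.20) and Fabp7, a fatty acid binding protein (-1.97, SE 0.31), were lower in ko. Pancreas genes had a median of -2.46 with 0 of 10 called and 6 lower when adjusted over the list alone (adjusted p = 0.35 with an estimated correlation), and -0.43 without wt replicate 2, where Ctrb1 was at 28254. Without that array the camera call of the list was lost (adjusted p = 0.211). The count of 621 was 277, 246 and 161 without ko replicates 1, 2 and 3, and 274, 991 and 245 without wt replicates 1, 2 and 3, and all 20 genes named by rule kept their calls in each of these fits except Rag1. With the array set as a block 802 probe sets were called, including all 621, while 276 were called within the low set and 84 within the high set. In the low set 1 ko array is compared with 1 wt array. The spread there comes from the ko arrays at 1 month, and the count rests on no replicates at this age.

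**Figure D3:**
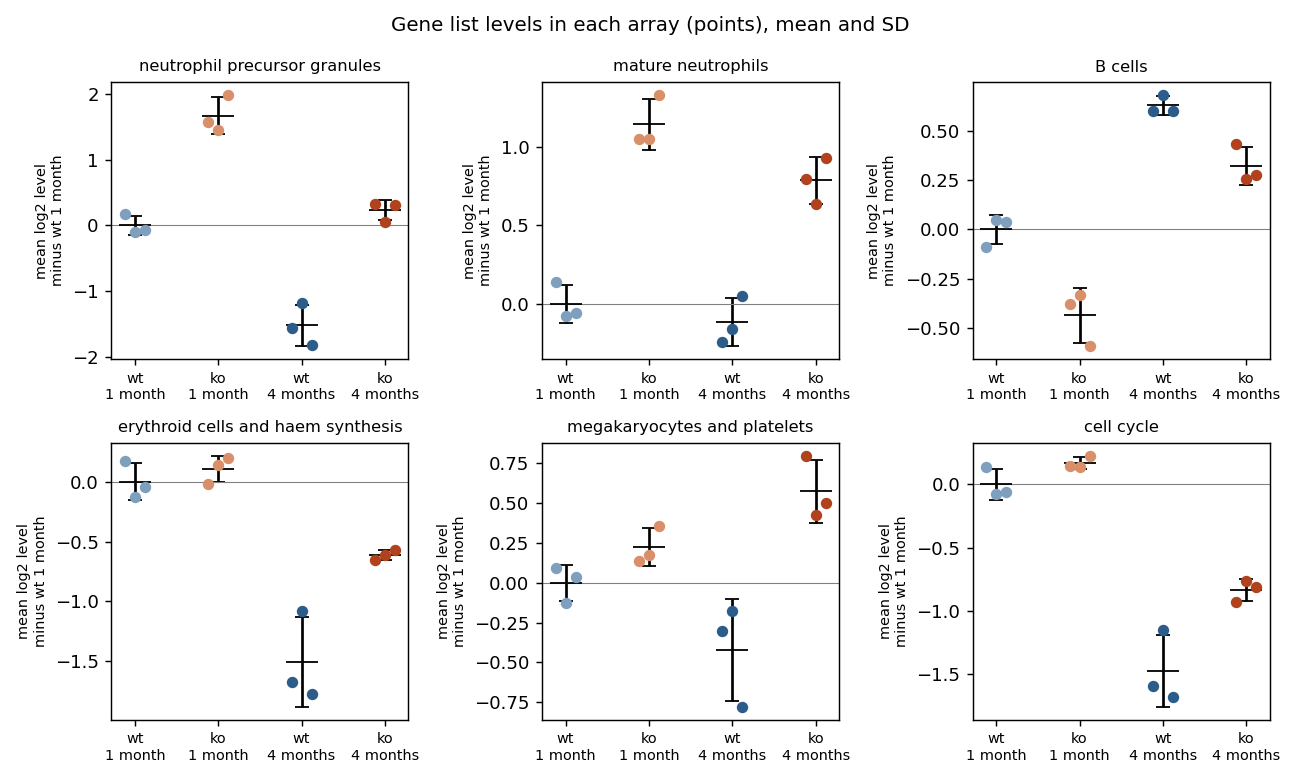
Mean log2 level of the measured genes of 6 lists in each array (points), minus the mean of wt at 1 month, with the mean (bar) and SD (whiskers) of the 3 mice of each group. Neutrophil precursor genes have a mean of 1.67 in ko at 1 month, 0.23 in ko at 4 months and -1.52 in wt at 4 months, with wt at 1 month at 0; erythroid genes reach -1.51 in wt and -0.61 in ko at 4 months.

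The genotype effects at the 2 ages overlapped. Among the probe sets called higher, 30 were shared between the ages, against 0.978 if the calls were independent (Fisher's exact p = 2.64e-38), and among those called lower 13 were shared, against 0.337 (Fisher's exact p = 1.42e-17). These values treat probe sets as independent, though some genes have several. Both contrasts also share the variance estimate of each probe set, so the values describe the overlap and are no valid test of it. No probe set was called in opposite directions, with 0 found against 0.285 and 1.16 if independent. Across all 27041 probe sets, which are not independent replicates, the log2 differences at the 2 ages had Pearson's r = 0.32 and Spearman's rho = 0.312. Shared higher genes beyond those named so far included Olfm4, Mmp8, Fcnb, Slfn4 and Zhx2, picked from the overlap after it was seen, with log2 differences over both ages of 1.84, 1.66, 1.57, 1.45 and 1.68. The shared lower genes besides Il1rn were Oas1a, Oas1b, Ctps2, G530011O06Rik, Dnah8, Sesn3, Cmah, Zfp148 and Rtf2, the last 5 chosen after their values were seen, and the last 5 lay between -0.79 and -0.99 over both ages.

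Over both ages together, 6 ko against 6 wt mice, 1457 probe sets were called, 766 higher and 691 lower in ko, and of the 103 that differed at least 2-fold 76 were higher and 27 lower. The largest shared increases were Lcn2 at 3.03 (SE 0.23), Prtn3 at 2.92 (SE 0.17), Ltf at 2.55 (SE 0.19), Elane at 2.55 (SE 0.28) and Mpo at 2.54 (SE 0.18). With the offset of 32, the largest decreases were Oas1a at -3.16 (SE 0.22), Oas1b at -2.81 (SE 0.25), Ctps2 at -2.43 (SE 0.14), Il1rn and G530011O06Rik at -1.90 (SE 0.25). Of B cell genes, 13 of 25 were called lower and 19 when adjusted over the list alone (median -0.43, adjusted p = 0.0792 with an estimated correlation). Without 1 array the count of 1457 ranged from 407 (without ko at 1 month replicate 3) to 2901 (without wt at 1 month replicate 3). It was 671 without ko at 1 month replicate 2, 719, 688 and 555 without ko at 4 months replicates 1, 2 and 3, 469 without wt at 1 month replicate 2, and 734 and 877 without wt at 4 months replicates 1 and 3.

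**Figure D4:**
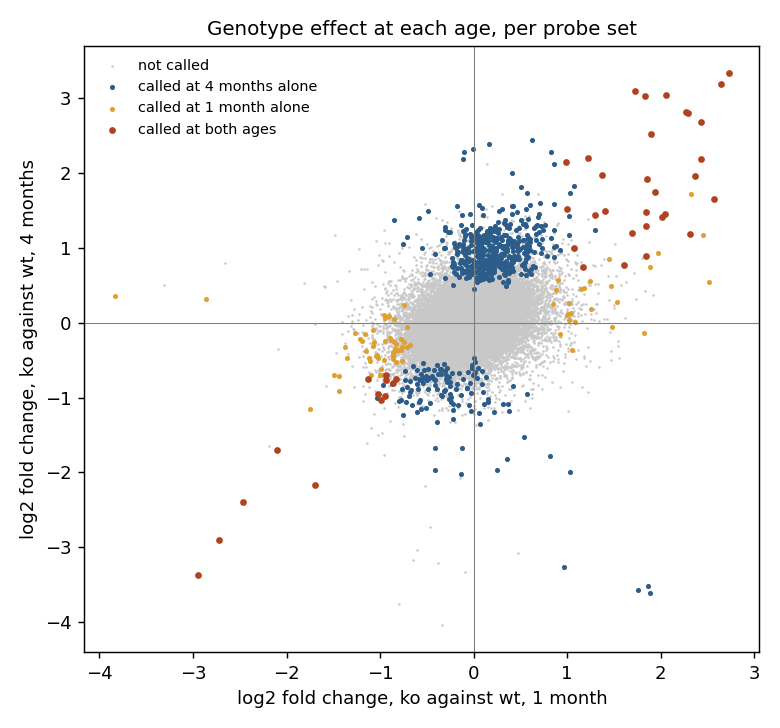
Log2 difference of ko against wt at 1 month (horizontal axis) and at 4 months (vertical axis) for each of the 27041 probe sets tested, with colour for the probe sets called at 1 age or at both. The 30 probe sets called higher and the 13 called lower at both ages lie in the upper right and lower left.

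The difference of the genotype effect between the ages, which is the test of phase specificity, was called for 13 probe sets, 8 more positive and 5 more negative at 4 months. Mcpt4 fell in ko at 1 month, from 352 ± 62.6 to 20.4 ± 5.6 (SD, n = 3), and stood at 269 ± 95.7 in wt and 338 ± 92.6 in ko at 4 months, a difference between the effects of 3.18 (SE 0.37, limma adjusted p = 0.00596). Ighg3 (2.39, SE 0.35) and Ighm, the IgM heavy chain constant region (2.30, SE 0.30), had similar levels in both genotypes at 1 month, and at 4 months Ighm reached 6660 ± 1733 in ko against 1397 ± 94.7 in wt. Probe sets of immunoglobulin genes can detect related transcripts. Also called were 6030468B19Rik (2.22, SE 0.36), Apol8 (1.52, SE 0.25) and, named after their values were seen, Rsad2, an interferon-induced antiviral gene (1.47, SE 0.23, limma adjusted p = 0.0278), and Cyp4b1, a cytochrome P450 (1.21, SE 0.19, limma adjusted p = 0.0253). The negative side was Hspa1b (-5.34, SE 0.67), Hspa8 (-2.22, SE 0.35) and Dnajb1 (-1.26, SE 0.21). Hspa1b stood at 450 ± 296 in wt and 1376 ± 140 in ko at 1 month, and at 6519 ± 5799 and 404 ± 82.4 at 4 months.

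Of the lists, 9 passed camera for this difference. Monocyte and macrophage genes (median 0.43, with 0 of 28 called and 3 higher when adjusted over the list alone) held with an estimated correlation (adjusted p = 0.0429). Cd5l, a protein of splenic macrophages, differed by 0.91 (SE 0.21) and the scavenger receptor Cd163 by 0.76 (SE 0.20), neither of them called. Erythroid genes (0.85, 0 called and 27 higher when adjusted over the list alone) and megakaryocyte genes (0.93, 0 called and 12 higher when adjusted over the list alone) both had an adjusted p = 0.15 with an estimated correlation. Cell cycle genes had a median of 0.52, 0 called and 8 higher when adjusted over the list alone (adjusted p = 0.306 with an estimated correlation). The neutrophil precursor list did not pass, with a median of -0.36 and a mean of 0.08. The count of 13 was 5, 5 and 8 without ko at 1 month replicates 1, 2 and 3, 6 and 7 without ko at 4 months replicates 1 and 2, 48 without wt at 1 month replicate 3 and 92 without wt at 4 months replicate 2. Hspa1b, Ighm and Mcpt4 kept their calls without each array in turn, while Apol8 lost its call in 10 of 12 such fits, Hspa8, Rsad2 and Cyp4b1 in 9, Dnajb1 and 6030468B19Rik in 8, and Ighg3 in 2, those without ko at 1 month replicate 1 or 2 (limma adjusted p = 0.0652 at most). The replicate block ended the calls of 6030468B19Rik, Apol8 and Dnajb1 (limma adjusted p = 0.0505, 0.0505 and 0.0651). The array set as a block ended those of Apol8, Dnajb1, Hspa8 and Cyp4b1 (0.111, 0.0891, 0.0993 and 0.0802). An offset of 1 ended those of Apol8 and Dnajb1 (0.0502 and 0.0507), and an offset of 64 that of 6030468B19Rik (0.0678). Without a trend in eBayes 1 probe set was called, a positive one. Hspa1b therefore lost its call there, and at most 1 of Ighm and Mcpt4 kept it. With robust hyperparameters 8 were called higher and 2 lower, so not all 3 probe sets of Hspa1b stayed called.

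Between 1 and 4 months, wt spleens came to hold less transcript of dividing cells and more of plasma cells. With the preset correlation but not with an estimated one, they also held less of erythroid and neutrophil precursor cells and more of B and T cells. All 37 erythroid genes were called lower, also when adjusted over the list alone, with a median of -1.55 (adjusted p = 0.0548 with an estimated correlation), among them Rhag (-1.76, SE 0.16), Urod (-1.69, SE 0.16), Ank1 (-2.26, SE 0.21) and Tal1 (-1.62, SE 0.16). Of 63 cell cycle genes, 62 were called lower, also over the list alone, with a median of -1.53 (adjusted p = 0.0425 with an estimated correlation), among them Ect2 (-1.96, SE 0.15), Kif11 (-1.97, SE 0.17) and Bub1 (-1.83, SE 0.16). Of 17 neutrophil precursor genes, 13 were called lower and 1 higher, with a median of -2.15 (adjusted p = 0.0834 with an estimated correlation) and 14 lower and 2 higher when adjusted over the list alone. The called increase was Cybb (0.95, SE 0.14), a subunit of the phagocyte NADPH oxidase that macrophages also express. Camp fell by 2.97 (SE 0.21), Elane by 2.97 (SE 0.39), Ctsg by 2.61 (SE 0.21), Ngp by 2.55 (SE 0.24), Prtn3 by 2.54 (SE 0.24) and Mpo by 2.52 (SE 0.25). In all, 5795 probe sets were called, 3179 higher and 2616 lower at 4 months, while of the 1684 that differed at least 2-fold 566 were higher and 1118 lower.

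Plasma cell and immunoglobulin genes rose in wt, with 12 of 25 called higher and 1 lower, 13 and 1 when adjusted over the list alone and a median of 0.54 (adjusted p = 0.0425 with an estimated correlation). Igha, the IgA heavy chain constant region, rose 10.9-fold, from 1194 ± 329 to 13998 ± 6082 (SD, n = 3), and Ighm (a different probe set) rose by 2.91 (SE 0.28), while Ell2 fell by 0.92 (SE 0.17). B cell genes were called higher for 20 of 25 and lower for 1, against 21 and 1 when adjusted over the list alone, with a median of 0.63 (adjusted p = 0.0834 with an estimated correlation). Cr2 rose by 1.13 (SE 0.15) and Cxcr5, a follicle homing receptor, by 0.91 (SE 0.16), while Cd24a, which erythroid cells also express, fell by 0.83 (SE 0.19). T cell genes were called higher for 14 of 27 and for 20 when adjusted over the list alone (median 0.58, adjusted p = 0.156 with an estimated correlation), Il7r by 0.82 (SE 0.16) and Cd4 by 1.12 (SE 0.23). Monocyte and macrophage genes were called higher for 16 of 28 and 19 when adjusted over the list alone (median 0.54, adjusted p = 0.0425 with an estimated correlation), with Hmox1, a haem-degrading enzyme, at 1.20 (SE 0.17) and Spic, a transcription factor of red pulp macrophages, at 0.78 (SE 0.16). Inflammatory genes were called higher for 9 of 20 and lower for 1, against 13 and 1 when adjusted over the list alone (median 0.57, adjusted p = 0.0425 with an estimated correlation), among them Nfkb2 (1.27, SE 0.24) and Ccl5 (0.98, SE 0.20), while Sod2 fell by 0.40 (SE 0.13).

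Other large changes in wt were increases of Hspa1b (3.98, SE 0.52), Hspa1a (3.11, SE 0.55), Npy1r (2.22, SE 0.37), Igkv14-111 (2.20, SE 0.44), Parm1 (2.09, SE 0.41) and Itsn2 (2.03, SE 0.29). Decreases were called for Tyrp1 (-3.68, SE 0.67), 6030468B19Rik (-3.29, SE 0.26), Dmtn, a red cell membrane protein (-2.75, SE 0.28), and Apol8 (-2.46, SE 0.18). The pancreatic proteases Prss2 (3.88, SE 1.25) and Cela3b (3.59, SE 1.15) were also called, and without wt at 4 months replicate 2 they were at 1.52 (limma adjusted p = 0.0808) and, still called, at 1.36. Without wt at 1 month replicates 1, 2 and 3 their calls were also lost (limma adjusted p = 0.089, 0.0664 and 0.0778 for Prss2 and 0.0963, 0.0824 and 0.0512 for Cela3b). The median log2 difference over all probe sets was 0.09 as scaled and -0.03 with median centring, and the share of calls that were increases was 54.9% and 35.9%. Without wt at 1 month replicate 1 the count was 3492.

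In ko, 6187 probe sets were called between the ages, 3685 higher and 2502 lower at 4 months, and 919 and 540 at 2-fold or more. This contrast lies partly along the array set, since ko had 3 low arrays at 1 month and 1 low and 2 high arrays at 4 months. With the set as a block 4948 were called, 4333 of them among the 6187. For age in wt that block kept 5787 of 5795. The largest increases were immunoglobulin genes: a further probe set of Ighm rose by 4.68 (SE 0.24), Ighg3 by 4.11 (SE 0.25) and a second probe set of Igha by 3.63 (SE 0.27). Dbp, a clock-controlled transcription factor, rose by 3.07 (SE 0.22), from 114 ± 12 to 1197 ± 55.7 (SD, n = 3). Neutrophil precursor genes were called lower for 14 of 17 and higher for 1, also when adjusted over the list alone, with a median of -1.76 (adjusted p = 0.0519 with an estimated correlation), with Chil3 at -2.59 (SE 0.22), Ms4a3 at -2.13 (SE 0.25) and, as the increase, Cybb at 0.53 (SE 0.14). Erythroid genes were called lower for 25 of 37 and 31 when adjusted over the list alone, with a median of -0.76 (adjusted p = 0.12 with an estimated correlation), and cell cycle genes for 59 of 63 and 61 when adjusted over the list alone, with a median of -1.0 (adjusted p = 0.0519 with an estimated correlation).

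Monocyte and macrophage genes rose in ko, with 23 of 28 called, also over the list alone, and a median of 1.06 (adjusted p = 0.00628 with an estimated correlation), Cd163 by 1.30 (SE 0.14) and Cd5l by 1.29 (SE 0.15). Endothelial genes rose with 18 of 24 called, 20 over the list alone and a median of 0.73 (adjusted p = 0.0228 with an estimated correlation), Pecam1 by 1.40 (SE 0.18). The plasma cell list (13 of 25 higher and 1 lower; 17 and 1 when adjusted over the list alone; median 0.63) and the inflammatory list (9 of 20 higher and 1 lower; 11 and 1 over the list alone; median 0.57) both held with an estimated correlation (adjusted p = 0.0398). Mcpt4 rose by 2.80 (SE 0.26). Car3 (2.84, SE 0.85), Rag1 (-2.34, SE 0.41), Kbtbd6 (-2.08, SE 0.47) and Mogat2 (-2.05, SE 0.38) completed the genes named by rule, and Car3 lost its call without ko at 1 month replicate 2 or 3 or ko at 4 months replicate 1 or 3 (limma adjusted p = 0.107, 0.0816, 0.0867 and 0.0889). Between the genotypes, 1884 probe sets rose with age in both, against 433 if independent, and 1587 fell in both, against 242. With median centring the median over all probe sets moved from 0.10 to -0.06, and 35.8% of calls were increases instead of 59.6%. Without ko at 4 months replicate 1 the count was 3653 and without replicate 3 it was 4018.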

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

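The tests of the genes lower in ko at both ages, of the neutrophil precursor genes within an array set, of the array set at 4 months and of the heat shock genes were chosen after the result was seen, and the criteria for a single wt array, for handling and for the neutrophil precursor genes were rewritten once their values were known. The genotype effect differed between the ages, by a test of the difference itself, for 13 probe sets of 10 genes: Mcpt4 (3.18), Ighg3 (2.39), 2 probe sets of Ighm (2.33 and 2.30), 6030468B19Rik (2.22), Apol8 (1.52), Rsad2 (1.47) and Cyp4b1 (1.21) on the positive side, and 3 probe sets of Hspa1b (-5.50, -5.39 and -5.34), Hspa8 (-2.22) and Dnajb1 (-1.26) on the negative side, as log2 differences. By camera it differed for the lists of erythroid cells (median 0.85), megakaryocytes and platelets (0.93), both with an adjusted p = 0.15 with an estimated correlation, the cell cycle (0.52; adjusted p = 0.306 with an estimated correlation), monocytes and macrophages (0.43; adjusted p = 0.0429 with an estimated correlation), endothelial cells (0.41; adjusted p = 0.0834 with an estimated correlation), MHC class II antigen presentation (0.35; adjusted p = 0.534 with an estimated correlation), interferon-stimulated genes (0.17; adjusted p = 0.633 with an estimated correlation), pancreas genes (-2.10; adjusted p = 0.534 with an estimated correlation) and immediate early and heat shock genes (-0.22; adjusted p = 0.15 with an estimated correlation). The pancreas value was -0.16 without wt at 4 months replicate 2 (camera adjusted p = 0.5). The MHC class II call was lost without ko at 1 month replicate 3 or wt at 4 months replicate 1 (camera adjusted p = 0.164 and 0.0707). The interferon call was lost without ko at 1 month replicate 3, wt at 1 month replicate 2 or wt at 4 months replicate 1 or 2 (camera adjusted p = 0.293, 0.378, 0.0817 and 0.102).

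Of 100 splits of the 12 arrays within each age, out of 200 possible, 5 gave at least the 13 calls of this difference, the real one included, so chance is not excluded for that count. The highest of the other splits gave 1457. That split swaps the genotypes at 1 age and so measures the effect shared by both ages, which is a structure of the samples, and the next highest gave 94. Leaving that swap out, which was decided after the result was seen, 4 of 99 splits gave at least 13 calls, the real one included. For genotype over both ages 1 of 100 splits, the real one, gave 1457 calls and the highest other gave 21, which argues against chance there. With 100 splits no share under 1 in 100 could be shown. The splits also do not separate genotype from the array set at 1 month. At a single age the 10 splits of 6 arrays are too few for a share under 0.05: the real split gave 120 calls at 1 month and the highest other 0, 621 at 4 months and the highest other 0, 5795 for age in wt and the highest other 31, and 6187 for age in ko and the highest other 0, with 1 split of 10 reaching the real count in each case.

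The calls of genotype at 1 month lie partly along the array set, since all 3 ko arrays and 1 of 3 wt arrays are in the low set, and without that wt array (replicate 3) genotype and set coincide and 1590 were called. With the set as a block 45 probe sets were called instead of 120: 43 were kept, with a median size of 1.84 (median SE 0.22) before and 1.89 (median SE 0.24) after, and 77 were lost, with 1.01 (median SE 0.19) before and 0.91 (median SE 0.22) after, so a slightly smaller difference and a larger SE ended those calls. At 4 months, where each genotype holds 1 low and 2 high arrays, the low minus high difference of the 120, signed by their direction at 1 month, had a median of -0.0372 (SD 0.26) against 1.12 for genotype at 1 month, and it reached 50% of the genotype difference in 0 of 120. If the set acts alike at both ages it is argued against as the whole cause of these calls. For the higher neutrophil precursor genes at 4 months that condition is not needed. A set effect alike in both genotypes cancels there, so the design itself argues against it. The fit with the set as a block could only return the same median, 1.95. Within the high set, 2 ko against 2 wt arrays, the median was 2.02 (mean 1.69, SE 0.19 over the arrays). For the 77 lost calls a set effect confined to 1 month and genotype cannot be told apart, since within the low set only 1 wt array is left, and a biological difference stays open as untested.

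Besides Il1rn, 9 genes were called lower in ko at both ages, Oas1a, Oas1b and Ctps2 among them. DNA of the strain that carried the altered Il1rn could remain around that gene, but 0 of the 9 lie among its 305 neighbouring genes (105 before and 200 after it), which argues against it for them. Over both ages the odds ratio of a call among the neighbours was 0.993 (95% interval 0.597 to 1.56), and this interval leaves such DNA open for part of the calls near Il1rn. DNA of another strain elsewhere in the genome may also lower such genes: 1 pair of the 9, Oas1a and Oas1b, lies within 20 genes of each other, as in 0.0334 of 10000 random sets, while among protein-coding genes, which leave out Oas1b, there were 0 pairs. The version with genes of every biotype was added after that 0 was seen, and the pair was known beforehand to be adjacent, so it decides nothing and strain-derived DNA and an effect of the missing Il1rn cannot be told apart for these genes.

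Heat shock genes were lower in ko than in wt at 4 months, with a median of -0.55 over 12 genes, all 12 negative (camera adjusted p = 1.04e-12, and adjusted p = 0.0649 with an estimated correlation). With the eBayes trend, a genotype effect common to both ages is argued against for Hspa1b. Its difference between the ages was called by limma and stayed called without each array in turn. Without the trend, 1 probe set was called for this difference, a positive one, so Hspa1b lost its call and the argument depends on that choice. At 1 month the median of the 12 genes was 0.31, with 11 of 12 positive (adjusted p = 0.347 with an estimated correlation). By limma, 2 of the 12 were called for the difference between the ages. As a list, that difference had an adjusted p = 0.0230 with an estimated correlation. The list was split off after the data were seen, and its p was adjusted over the added lists alone. The fixed list did not pass with an estimated correlation, so this p is no separate support. A single wt array is argued against as the whole cause, since without wt replicate 3 all 5 called genes stayed called lower and 11 of 12 stayed negative (p = 0.00579 with an estimated correlation, not adjusted), though the median shrank to -0.28, so that array may carry part of the size. Stress or handling that also raises immediate early genes could contribute too, and their median was -0.0855 at 4 months (13 of 19 negative; camera adjusted p = 0.0132, and adjusted p = 0.135 with an estimated correlation). At 1 month the median of the immediate early genes was -0.0387 (11 of 19 negative). Their difference between the ages was 0.0265 (11 of 19 positive; camera adjusted p = 0.274). The shift at 4 months passes only with the preset correlation, and either cause could give such a shift. Handling and a genotype effect at 4 months therefore cannot be told apart, and the biological difference is untested.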

How the results depend on the processing

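The array set settings, and Il1rn under the settings that only counted calls before, were chosen after seeing the data. The counts for the 6 contrasts are, in order, 120, 621, 1457, 13, 5795 and 6187 for genotype at 1 month, at 4 months and over both ages, for its difference between the ages, and for age in wt and in ko. Settings not printed left a count within 1.5 times of these. No filter gave 77 at 1 month, 795 over both ages and 8 for the difference, and eBayes without a trend gave 68, 248 and 555 for genotype at 1 month, at 4 months and over both ages and 1 for the difference. Array weights gave 30 for the difference, 3680 for age in wt and 11052 in ko. By construction, an added limit of 2-fold lowered counts, to 259 at 4 months, 103 over both ages, 1684 in wt and 1459 in ko, and an adjusted p under 0.10 raised them, to 392, 1092 and 2918 for genotype and 31 for the difference. Only the 6 arrays compared gave 47, 362, 3186 and 8911 for genotype at 1 month, at 4 months, age in wt and age in ko. The low set gave 32, 276 and 153 for genotype, 1559 for age in wt and 2470 for age in ko, and the high set gave 84 at 4 months and 3761 for age in wt. The array set as a block gave 45 at 1 month, and with the replicate block 41 at 1 month, 755 over both ages and 3692 for age in ko. The replicate numbers do not pair the mice, and as a block they gave 109, 563, 1299, 14, 5470 and 5840. Leaving out each array in turn gave 36 to 1590 at 1 month, 161 to 991 at 4 months, 407 to 2901 over both ages, 5 to 92 for the difference, 3492 to 6375 for age in wt and 3653 to 5332 for age in ko. Where a group then held 2 arrays, limma pooled the spread over all groups.

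Of 83 list calls, 16 were kept with an estimated correlation, 59 with fry, 83 with the replicate block, 81 with quantile normalization, 79 with the array set as a block and 80 with either other choice of probe set. The call of Il1rn at 1 month was lost with quantile normalization (-1.64), median centring (-1.67), offsets of 1 (-2.91) and 8 (-2.44), no filter (-1.70), array weights (-1.50), only the 6 arrays compared (-1.70), the replicate block (-1.70), the array set as a block (-1.67), both blocks (-1.77) and in the low set (-1.51). At 4 months it was lost in the low (-2.88) and the high set (-1.82). That of its second probe set over both ages was lost with no filter (-0.85), the array set as a block (-0.71), both blocks (-0.77) and in the low set (-0.68). The filter at 200 leaves out Il1rn. Without each array in turn the first probe set was -1.92 to -1.45 at 1 month and the second -0.95 to -0.72 over both ages. Values that changed sign were uncalled: Il1rn for age in ko (-0.03) was 0.0365 with an offset of 1, 0.0434 with both blocks and -0.28 to 0.19 without 1 array, its second probe set for age in wt (0.18) was -0.0668 to 0.37, and its remaining probe set, called in no contrast, was -0.39 to 0.66, -0.14 with array weights and -0.82 in the low set for the difference (0.19), and -0.20 to 0.85 and, in the high set, -0.62 for age in wt (0.27). For age in wt 1 probe set of Ttn (0.51) was -0.00358 to 0.84. With quantile normalization the share of increases went from 45.8% to 57.7% at 1 month, and with median centring to 62.4% there, from 61.5% to 47.4% for the difference, from 54.9% to 35.9% for age in wt and from 59.6% to 35.8% in ko. Apart from the limits, the cause was not tested. Signal over background limits low transcripts: the offset of 32 shrinks their differences, as the Il1rn values with offsets of 1 and 64 (-1.26) show.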

Other observations

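The tests of the clock, melanocyte and heat shock lists were chosen after the result was seen, and the other lists were planned. Clock-controlled genes stood higher in ko at 4 months, with a median log2 difference of 0.71 and 10 of 10 positive, although 0 were called by limma (camera adjusted p = 0.0207 with an estimated correlation). The difference between the ages was 1.01 and the rise from 1 to 4 months in ko 1.16, with 7 called. The probe set that stands for Dbp in this list was at 730 ± 159 (SD, n = 3) in wt and 1235 ± 67.6 in ko at 4 months. The probe set of Dbp named above for age in ko was at 585 ± 198 in wt and 1197 ± 55.7 in ko. Arntl, which peaks at the opposite time of day, was at 642 in wt and 388 in ko at 4 months. The 3 opposite-phase genes had a median of -0.62, and no test was run on so few. The times at which the spleens were taken were not used here.

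Lists of genes related to IL-1 signalling or to joint inflammation passed no camera test of genotype at either age. The mean levels of 3 of them did not overlap between ko and wt: inflammatory genes at 1 month (-0.231 to -0.0596 in ko and -0.0496 to 0.0491 in wt) and at 4 months (0.346 to 0.472 and 0.508 to 0.529), bone genes at 1 month (-0.146 to -0.138 and -0.0619 to 0.0970) and complement genes at 4 months (0.656 to 0.831 and 0.300 to 0.498). Chance gives 10% per list and age, but 19.9% of all tested probe sets at 1 month and 22.3% at 4 months did not overlap either. The IL-1 family list had a median of -0.06 at 1 month (camera adjusted p = 0.668) and -0.02 at 4 months (0.417), with 0 of 27 called by limma at either age and 1 lower and 0 when adjusted over the list alone. Inflammatory cytokines, chemokines and NF-kB targets were at -0.17 (0.167) and -0.12 (0.232), with 0 of 20 called at either age and 2 lower and 0 over the list alone. T helper 17 genes were at -0.15 (0.196) and 0.05 (0.76, the test pointing down), with Ccr6 lower at 1 month (-0.84, SE 0.18), named after its value was seen. Bone and cartilage genes were at -0.25 (0.0776) and 0.05 (0.863), with Mmp9, a neutrophil protease named after its value was seen, higher at 1 month (1.45, SE 0.24). Complement and acute phase genes had medians of -0.13 (0.857) and -0.01 (0.15) but means of 0.22 and 0.35, carried by the neutrophil genes Lcn2 and Lrg1 and at 1 month by Hp, while Cr2 was lower.

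Further lists passed no test of genotype at either age, given as 1 month then 4 months with camera adjusted p: plasma cells -0.02 (0.927) and -0.01 (0.863, mean 0.04), NK cells -0.07 (0.857) and 0.02 (0.637, the test pointing down), adipose tissue -0.30 (0.271) and 0.02 (0.637), skeletal muscle 0.03 (0.867) and 0.18 (0.42), and mast cells, basophils and eosinophils 0.10 (0.691, the test pointing down) and 0.17 (0.863). Interferon-stimulated genes were at -0.14 (0.188) and 0.11 (0.157). At 1 month erythroid genes were at 0.07 (0.126), germinal centre B cells -0.27 (0.18), pancreas -0.42 (0.857) and immediate early and heat shock genes 0.06 (0.44). At 4 months MHC class II genes were at -0.04 (0.157), dendritic cells -0.17 (0.07) and endothelial cells 0.15 (0.135), with Vwf, a platelet and endothelial adhesion protein named after its value was seen, higher in ko (1.17, SE 0.20). Sex-linked transcripts, which were not tested as a list, lay between -0.21 and 0.20 in mean log2 deviation, which averages Xist with Y-linked genes. The Y-linked Kdm5d was at 507 to 836 and Uty at 367 to 614 in all 12 arrays, and Xist at 89.8 to 377. At 4 months Xist did not overlap between ko (183 to 221) and wt (89.8 to 98.3), as did 22.3% of all tested probe sets. At 1 month it was at 263 to 377 in ko and at 336, 96.8 and 108 in wt replicates 1, 2 and 3.

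With age, lists not described so far rose in both genotypes by camera but not with an estimated correlation. In wt and in ko these were MHC class II genes (0.54 and 0.82; adjusted p = 0.156 and 0.0712 with an estimated correlation), dendritic cells (0.67 and 0.71; 0.156 and 0.108), NK cells (0.56 and 0.65; 0.143 and 0.114), complement (0.67 and 0.89; 0.187 and 0.12) and adipose tissue (1.12 and 1.27; 0.329 and 0.166). The adipose call in wt was lost without wt at 1 month replicate 1 or wt at 4 months replicate 1 or 3 (camera adjusted p = 0.115, 0.0712 and 0.136). In ko B cells (0.84; 0.0712), T cells (0.74; 0.108), stroma (0.43; 0.504) and bone genes (0.37; 0.0911) did so too. Germinal centre B cells rose in wt (0.64), where the call held (0.0425), and in ko (0.55; 0.0943). In wt the IL-1 family (0.18; 0.187), immediate early and heat shock genes (0.49; 0.187), endothelial cells (0.31; 0.136) and pancreas genes (1.98; 0.497) were higher and megakaryocytes lower (-0.55; 0.305), while in ko megakaryocytes were higher (0.35; 0.514) and mature neutrophils lower (-0.63; 0.27). Of these, the IL-1 call was lost without wt at 1 month replicate 2 or 3 or wt at 4 months replicate 1 or 3 (camera adjusted p = 0.0627, 0.0934, 0.0839 and 0.0751), and the pancreas call without wt at 1 month replicate 2 or 3 or wt at 4 months replicate 2 (0.0503, 0.0934 and 0.563). Without wt at 4 months replicate 2 the pancreas median was 0.31. In ko, the megakaryocyte call was lost without ko at 1 month replicate 1 or 2 or ko at 4 months replicate 1 (0.0848, 0.0519 and 0.154), and the mature neutrophil call without ko at 1 month replicate 3 or ko at 4 months replicate 2 (0.0578 and 0.0784). Melanocyte genes differed by -1.84 at 1 month with 0 called by limma (adjusted p = 0.118 with an estimated correlation), from 2 wt arrays in which Dct was at 3099 and 1461, and the called probe set of Tyrp1 is not the one that stands for it in that list.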
